A study of Boehmeria nivea with 113 samples.

How the data were processed

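Leaves of 111 F2 libraries and 2 parents were analysed, each as 1 library and 1 replicate, with paired-end Illumina sequencing per the labels' protocols. Groups were taken from the source labels, and F2 libraries are named by the number in their title. The reads were aligned to the ramie genome by the authors, per the series' design text, and BWA and SAMtools are named in the submitters' processing notes without versions. The counting tool, genome build and annotation are not given in the sources used here. The deposited count table holds estimated counts, with decimals, of 30136 gene models, not scaled for depth. The deposited FPKM table holds the same gene models as fragments per kilobase, scaled to the library's reads. After 1 factor per library was divided out, the ratio of count to FPKM was constant within a gene model (median coefficient of variation 1.1e-05% over 6085 gene models). Another deposited table, with the counts and FPKM side by side, was not used, because its counts were displaced against the IDs, 28 rows were broken and 24 gene models had no counts. No column of per-sample values in the other tables was left unused.

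Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Gene models with a CPM of at least 1 in at least 10 libraries were kept (18657), scaled by TMM (factors 0.55 to 1.14), and fitted with 1 coefficient each for the F2, Qingyezhuma and Zhongsizhu 1 by the quasi-likelihood method. The contrasts were Qingyezhuma minus Zhongsizhu 1 and F2 minus the mean of the parents, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 library per parent, the spread came from the 111 F2 libraries alone. It holds segregating genetic differences besides plant-to-plant and technical spread, and each parent library was assumed to vary like an F2 library. A call therefore compares the parent libraries with the F2 spread. The standard error is the log2 difference divided by the root of the F statistic. Where a parent had no count, a floor of 3 counts in that library was used (0.174 CPM in Qingyezhuma, 0.238 CPM in Zhongsizhu 1), and the fold is a lower bound. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

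The spread in the F2 was the square root of the gene-wise edgeR dispersion of the F2 libraries. For presence and absence, TMM-scaled CPM of all gene models were used. A candidate had at least 20 CPM in 1 parent and less than 1/20 of that in the other, and an F2 library lacked it below 1/20 of the expressing parent. Shares have exact Clopper-Pearson 95% intervals and exact two-sided binomial tests against 25%, adjusted over the candidates. Co-absent sets were made from phi coefficients of at least 0.7 between candidates that were missing from at least 5 and present in at least 5 F2 libraries, a step chosen after seeing the data. The count of gene models with both parents outside the F2 range was also added then. Random pairs of F2 libraries, 22 for refits and 100 for counts, took the parents' place for comparison.

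The designs, alternatives and 23 gene lists were fixed before the data were examined. The lists were keyword patterns for protein descriptions (photosynthesis, cell wall, lignin, defence, stress and others), and none could be matched, because the files do not pair IDs with names. The comparisons of these lists between the parents and between F2 and parents, their spread and their co-variation were therefore not run. The rule for named genes asked for the largest log2 differences among called genes with a mean of at least 5 CPM and a described function, the largest and smallest spread among genes of at least 20 CPM, and the candidates with the highest CPM inside and outside 25%. It was applied without the description, with at most 2 IDs per direction.

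Of the gene models, 388 fell in 186 sets with identical counts in every library, which may not be told apart and held a median of 1.95% of a library's counts. No pair of libraries was a repeat: the smallest chi-square per gene model over 6328 pairs was 9.9, for a mean count of at least 20. In F2 samples 32, 42, 45 and 69 the table total per FPKM denominator was 39.4, 19.7, 18.4 and 47.5% of the median library, against 92.6 to 104.8% in the others. The edgeR calls, the count of gene models with both parents outside the F2 range and the missing shares were recomputed without these 4 libraries. This alternative was added after seeing the data, and the coefficients of variation in the F2 were not recomputed. Alternatives fixed beforehand were RLE size factors, other filters, DESeq2 1.42.0, limma 3.58.1 on log2 CPM (prior count 2) and on log2(FPKM + 1) and log2(FPKM + 0.1), robust fitting, subsets of F2 libraries, a principal component as covariate, a fold minimum, and other limits for absence.

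The scripts were tested on simulated counts, for the edgeR comparisons with the real means, dispersions and library sizes. For the parents, 48% of 50 gene models changed 4-fold and 68% of 50 changed 16-fold were found among 18483 in the fit, with 4 unchanged ones called. For F2 against parents, 68% of 50 and 94% of 50 were found, with 6 unchanged ones called. For segregation, 200 gene models were simulated for each share, and the interval held the true share for 97.5% at 25%, 94% at 50% and 94% at 75%. These had the real library sizes, the same dispersion for every gene model and no expression in the silent parent. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 were used for the shares and permutation tests, and matplotlib 3.10.9 for plots.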

Results

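RNA was sequenced from young leaves of ramie (Boehmeria nivea), a perennial bast fibre crop of the nettle family, at 30 days of growth. The data comprised 111 libraries of an F2 population and 1 library of each of its 2 parents, Qingyezhuma and Zhongsizhu 1. The population was sequenced to build a genetic map, and the same libraries gave expression values for 30136 gene models. Total estimated counts per F2 library ran from 1135995 to 18362522, with a median of 15929216, and were 16930309 in Qingyezhuma and 13628636 in Zhongsizhu 1. At least 1 count was found for 15578 to 19527 gene models per F2 library (median 18950), and 4423 gene models had no count in any library. The files do not pair gene model IDs with gene names or functions, so the results are given for groups of gene models and for a few IDs. The parents had no replicates, so no difference that rests on a parent has a replicate check.

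The first comparison asked which genes differed between the 2 parents. The gene model whole_GLEAN_10028815 was at 106.3 CPM in Qingyezhuma and 5.24 CPM in Zhongsizhu 1, a log2 difference of 4.34 ± 0.865 (SE; adjusted p = 0.0122, edgeR quasi-likelihood test). The F2 libraries held 71.997 ± 25.7 CPM of it (SD, n = 111), and the lowest of them, at 26.3 CPM, lay above Zhongsizhu 1. The gene model whole_GLEAN_10003917 was at 10.1 CPM in Qingyezhuma and had no count in Zhongsizhu 1, at least 42.4-fold higher against a floor of 3 counts (edgeR adjusted p = 0.0459), and was detected in every F2 library, at 5.61 ± 3.56 CPM (SD, n = 111). In the other direction, whole_GLEAN_10026230 had no count in Qingyezhuma and was at 66.5 CPM in Zhongsizhu 1, at least 382-fold higher (edgeR adjusted p = 0.0243). Its F2 level was 20.6 ± 13.4 CPM (SD, n = 111), and it had no count in 2 F2 libraries. On log2(FPKM + 1) values, and with only the F2 libraries of odd title number behind the spread, none of these 3 passed the threshold. Of 17 alternatives in all, the threshold was lost in 3 for whole_GLEAN_10028815, 6 for whole_GLEAN_10003917 and 2 for whole_GLEAN_10026230.

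These belonged to 11 called gene models of 18657 tested, 6 higher in Qingyezhuma and 5 higher in Zhongsizhu 1, and 8 of the 11 had no count in 1 of the parents. The mean log2 CPM of the F2 lay between the parents for 5 of the 11. It was closer to the higher parent in all, at a median of 1.06 (0.55 to 1.51) with the lower parent at -1 and the higher at 1. A difference that segregates widens the F2 spread behind the test, so the 11 do not measure how far the parents differ. The test thus favours gene models held at a steady level in the F2. Their position near the higher parent is therefore no test of how the difference is inherited. Unadjusted p-values under 0.05 were given by 1032 gene models, where 933 would arise with no effect. Without a test, 4735 gene models differed by more than 1 in log2 CPM between the parents, 2528 of them higher in Qingyezhuma, and 100 random pairs of F2 libraries differed in a median of 4305.5 (range 2862 to 9196). When 22 random pairs of F2 libraries took the place of the parents in the same fit, a median of 5 gene models was called (range 0 to 1096; the highest pair included F2 sample 45), and 5 of the 22 pairs gave at least as many as the parents. The count of called gene models was thus not beyond that between F2 libraries, and it moved from 2 to 41 with the tool and unit (41 with DESeq2, 5 of them shared with the edgeR calls, and 6 on log2(FPKM + 1) values, 0 of them shared).

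The second comparison set the F2 mean against the mean of the parents. The mean of the parents was taken on the log2 scale, where a gene model additive in CPM with unequal parents comes out higher in the F2. Both parents lay well above the F2 for whole_GLEAN_10025661, at 1427 CPM in Qingyezhuma and 656 CPM in Zhongsizhu 1 against 17.9 ± 15.8 CPM in the F2 (SD, n = 111; highest library 78.5 CPM). The log2 difference of F2 and parents was -5.75 ± 0.425 (SE; adjusted p = 8.46e-22, edgeR quasi-likelihood test). Likewise whole_GLEAN_10016669 was at 311 and 1096 CPM in the parents and at 12.3 ± 10.7 CPM in the F2 (SD, n = 111; highest library 76.99 CPM), with a log2 difference of -5.57 ± 0.34 (SE; edgeR adjusted p = 2.69e-27). Higher in the F2 were whole_GLEAN_10029958 and whole_GLEAN_10000695, which had no count in either parent. Their F2 levels were 11.6 ± 21.7 CPM and 10.5 ± 12.3 CPM (SD, n = 111), at least 56.2-fold and 51-fold above the mean floor of the parents (edgeR adjusted p = 0.0394 and 0.00782). These last calls were weak: neither passed the threshold against either parent alone in the same fit, nor on log2(FPKM + 1) values.

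**Figure D1:**
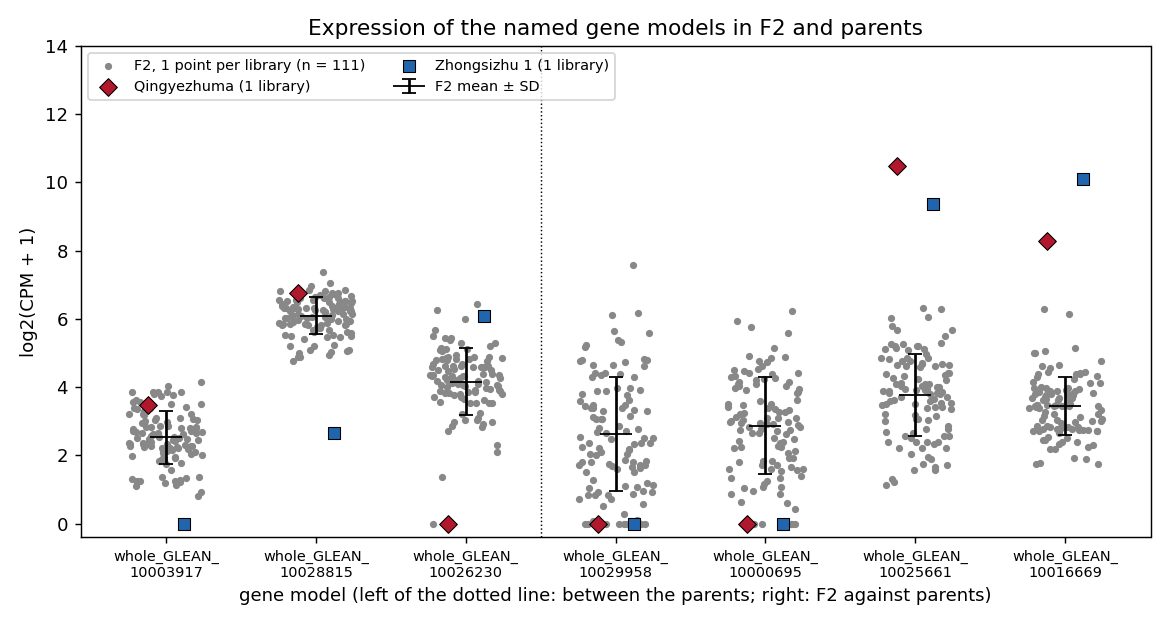
Expression of the named gene models as log2(CPM + 1) on the vertical axis, with 1 grey point per F2 library (n = 111), bars for the F2 mean ± SD, a red diamond for Qingyezhuma and a blue square for Zhongsizhu 1. Left of the dotted line at least 1 parent lies apart from most F2 libraries, and for whole_GLEAN_10025661 and whole_GLEAN_10016669 both parents lie above all 111 F2 libraries.

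In all, 3482 of 18657 gene models were called, 2001 higher and 1481 lower in the F2, and 5712 had an unadjusted p under 0.05. In CPM, the F2 mean was above both parents for all but 30 of those called higher, of which 2 were not above the mean CPM of the parents, and below both for all but 6 of those called lower. The calls were selected for their distance from the mean of the parents, which favours such an order, so these counts are no test of it. Over all tested gene models, both parents lay on the same side of the mean log2 CPM of the F2 in 68.6%. For the 6105 pairs of F2 libraries, each set against the mean of the other F2 libraries, the median was 50.3% (range 33.9 to 73.8%), and 0.2% of the pairs reached the parents' value. Both parents were above every F2 library for 470 gene models and below every F2 library for 426, where 2.9 per direction would arise if all libraries were exchangeable. Among 100 random pairs of F2 libraries the highest numbers were 40 and 44. On the deposited FPKM values 501 lay above and 38 below every F2 library, and 501 and 577 when F2 samples 32, 42, 45 and 69 were left out. Against each parent separately, the F2 differed from Qingyezhuma in 1071 gene models and from Zhongsizhu 1 in 1661. Of these, 228 were higher and 326 lower in the F2 in both comparisons and 0 changed in opposite directions, with 20 and 27 for independent lists. Both comparisons share the F2 libraries, and with random pairs of F2 libraries in the parents' place the overlap was 0 in either direction in all 22 pairs. In 8 pairs with adjacent title numbers it reached 2 higher and 28 lower. In most pairs of both kinds at least 1 of the libraries gave no call, so no overlap could arise, and these pairs set no firm level for it. The deviations of the parents from the F2 mean correlated across gene models at r = 0.29 (covariance 0.483), and at 0.29 again with each parent set against a separate part of the F2. The median over 6105 pairs of F2 libraries was -0.02 (covariance -0.017), and 1.7% of the pairs reached the parents' value. Gene models are not independent replicates, so no p-value is given for this correlation.

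The share of calls that were higher in the F2 depended on the scaling. The median log2 difference of F2 and parents over all gene models was 0.195 with TMM and 0.125 with RLE size factors, and 57.5% and 48.4% of the calls were higher in the F2. A shift of 0.104 arose in the unchanged gene models of simulated counts. The call count fell to 1161 on log2(FPKM + 1) values, with 446 higher and 715 lower.

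The third question was how much each gene model varied among the F2 libraries. The biological coefficient of variation, the edgeR estimate of spread beyond counting error, had a median of 0.36 over 18657 gene models, with 0.15 and 1.9 at the 5th and 95th percentiles. It was over 1 for 2770 gene models and under 0.2 for 3243. Among the 13555 gene models with a mean of at least 5 CPM the median was 0.28, and 707 were over 1. Among the gene models with a mean of at least 20 CPM in the F2, the steadiest were whole_GLEAN_10019063 (coefficient 0.081, 60.4 ± 4.69 CPM, SD, n = 111) and whole_GLEAN_10017025 (0.087, 103.6 ± 8.73 CPM, SD, n = 111). In the parents they were at 50.1 and 53.7 CPM, and at 96.8 and 96.5 CPM. The most variable at this level were whole_GLEAN_10000423 (coefficient 6.805) and whole_GLEAN_10001641 (6.108), which had no count in the parents and in 91 and 86 F2 libraries. Their highest levels, 2228 and 1446 CPM, were in F2 samples 45 and 42, whose total counts were the lowest and the second lowest. The F2 mean of whole_GLEAN_10000423, 34.9 CPM, was 15 CPM without F2 sample 45, and without F2 samples 32, 42, 45 and 69 the means of both were 2.76 and 0.7 CPM, below this level. Gene models that varied more in the F2 also differed more between the parents, with a Spearman rho across gene models of 0.36 within 10 bins of expression. The same value for pairs of F2 libraries had a median of 0.38 (range 0.21 to 0.45), so it did not set the parents apart.

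The fourth comparison asked whether expression present in 1 parent and missing in the other was missing in 25% of the F2, the share for 1 locus with a recessive silent allele when both parents are homozygous. The 174 candidates had at least 20 CPM in 1 parent and less than 1/20 of that in the other. An F2 library was counted as missing a gene model below 1/20 of the CPM of the expressing parent, so it could still hold counts. Of the candidates, 63 were expressed in Qingyezhuma and 111 in Zhongsizhu 1. The highest candidate whose interval held 25%, whole_GLEAN_10001175, was at 966 CPM in Zhongsizhu 1 and 3.31 CPM in Qingyezhuma and was missing in 35 of 111 F2 libraries (31.5%, exact Clopper-Pearson 95% interval 23 to 41%). The next, whole_GLEAN_10028886, was at 557 CPM in Zhongsizhu 1, had no count in Qingyezhuma and was missing in 24 of 111 (21.6%, 14.4 to 30.4%). Outside 25% lay whole_GLEAN_10000158, at 12957 CPM in Zhongsizhu 1 and 132 CPM in Qingyezhuma, missing in 39 libraries (35.1%, 26.3 to 44.8%; adjusted p = 0.0247, exact two-sided binomial test), and whole_GLEAN_10000145, at 8226 and 67.5 CPM, missing in 46 libraries (41.4%, 32.2 to 51.2%; adjusted p = 0.000328, same exact test). All of these but whole_GLEAN_10028886 belonged to the set of 29 co-absent gene models, and these 3 were detected in every F2 library, at 1.7, 21.9 and 1.2 CPM or more in the order given. The F2 mean of whole_GLEAN_10001175 was 4186 ± 10366 CPM (SD, n = 111), above its expressing parent. The SD exceeded this mean, and 35 libraries lay under 1/20 of that parent, so the mean does not describe a typical F2 library.

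Over all candidates the missing share had a median of 34.2% and ran from 0 to 100%. The interval held 25% for 53 candidates (30.5%), 50% for 42 and 75% for 10. Against 25%, 88 candidates were missing from more F2 libraries and 32 from fewer (Benjamini-Hochberg adjusted p under 0.05), and 54 did not differ from it. The candidates were not independent, since some had identical counts and many were missing from the same libraries. With 1 gene model kept per identical set, 21 of those missing from more libraries belonged to 1 co-absent set. Among the other candidates, 57 were missing from more and 31 from fewer. In simulated data with a true share of 25%, the interval held 25% for 97.5% of 200 gene models. That simulation had the same dispersion for every gene model and no expression in the silent parent. It therefore cannot tell how often 25% would be held for candidates picked from single parent libraries. The number of candidates was within that of pairs of F2 libraries, for which the same rule gave a median of 127 (range 26 to 403), and 21.1% of the 6105 pairs gave as many. With a minimum of 5 or 50 CPM in the expressing parent the interval held 25% for 134 of 466 and 26 of 88 candidates. The series' design text speaks of F2 families, and whether a library came from 1 plant is not given in the sources used here.

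**Figure D2:**
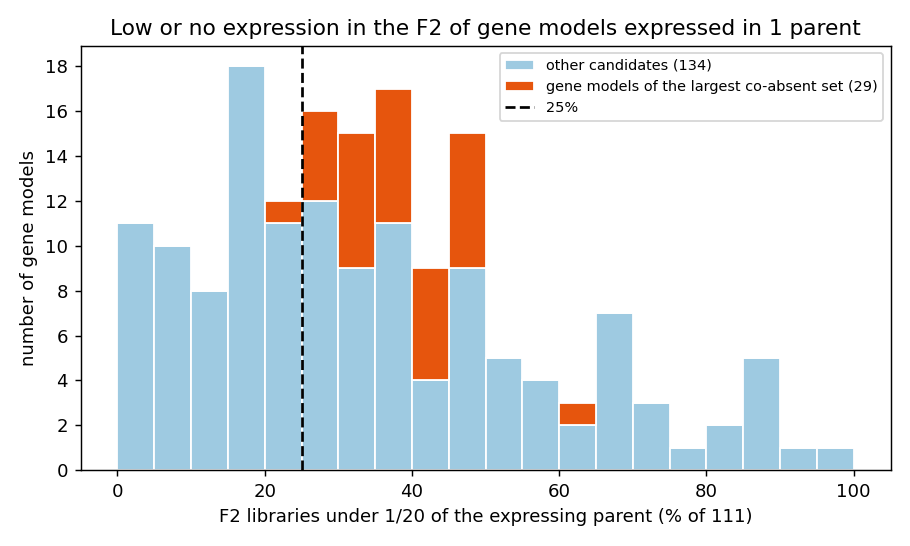
Histogram of the share of the 111 F2 libraries under 1/20 of the CPM of the expressing parent (horizontal axis, %) for 163 candidates, 1 per set of gene models with identical counts, with the number of gene models on the vertical axis. The dashed line marks 25%, and the 29 gene models of the largest co-absent set, in orange, have a median share of 38.7% against 28.4% for the other 134.

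Many candidates were missing from the same libraries. After 1 gene model was kept of each set with identical counts, 163 candidates remained, and 29 of them formed a set linked by phi coefficients of at least 0.7 (median over pairs 0.73). All 29 were expressed in Zhongsizhu 1. Their missing share had a median of 38.7% (24.3 to 63.1%), and 21 of the 29 were missing from more than 25% of the F2 (adjusted p under 0.05, exact binomial tests). Since the 29 were picked for being missing from the same libraries, these 21 are not separate results. Among the other 134 candidates the median was 28.4%, and the interval held 25% for 45 of them (33.6%). Smaller sets among these held 4, 4, 3 and 3 candidates, with median missing shares of 19.35, 29.7, 45.9 and 17.1% in that order. The set at 45.9% (median phi 0.73) joined both parents, with 1 of its 3 candidates expressed in Zhongsizhu 1 and the others in Qingyezhuma. The 29 gene models took 4.29% of the CPM of Zhongsizhu 1, 0.031% in Qingyezhuma and 0.032 to 26.2% in the F2 (median 0.99%). Their share was above that of Zhongsizhu 1 in 19 F2 libraries.

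**Figure D3:**
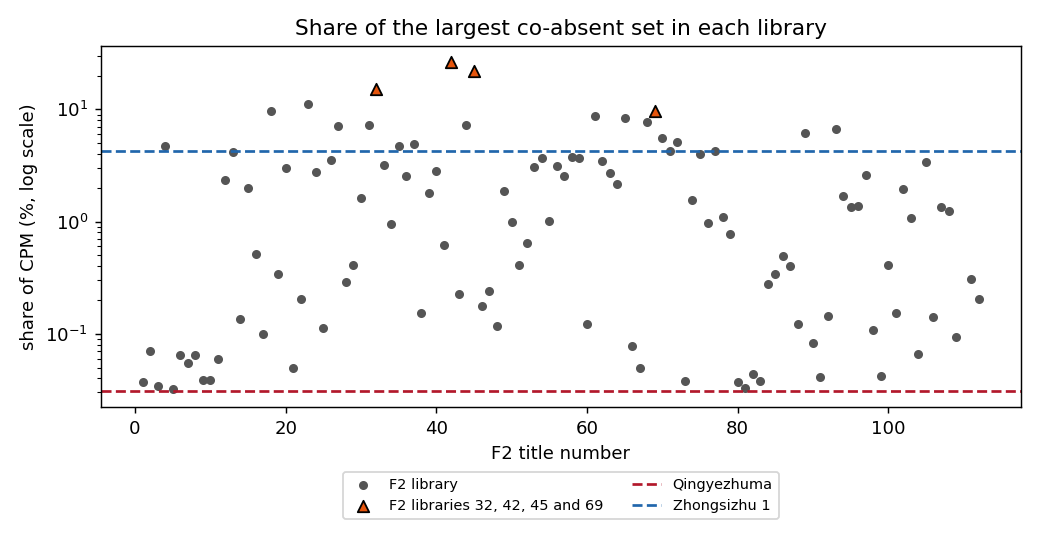
Share of CPM taken by the 29 gene models of the co-absent set (vertical axis, %, log scale) in each F2 library by title number (horizontal axis), with dashed lines for the parents. The F2 libraries fill the range between Qingyezhuma (0.031%) and Zhongsizhu 1 (4.29%) without a gap, and F2 samples 32, 42, 45 and 69, drawn as triangles, are among the highest.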

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

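Alternatives using the F2 title numbers up to 37 or from 75, the 4 libraries with a low table total, identical gene models, and the count of gene models outside the F2 range were chosen after seeing the data. The count between the parents, 11, stayed within 1.5 times under 9 of 17 alternatives. It was 41 with DESeq2 (5 shared with the 11), 24 with a principal component as covariate (11 shared), 24 with F2 title numbers up to 37 (11 shared), 20 with title numbers from 75 (9 shared), 6 on log2(FPKM + 1) (0 shared), 5 with odd title numbers only (4 shared), 3 with a mean of at least 5 CPM (3 shared) and 2 on log2(FPKM + 0.1) (1 shared). The count of F2 against parents, 3482, stayed within 1.5 times under 14 of 19 alternatives. It was 2104 with a log2 difference over 1, 1161 on log2(FPKM + 1) and 867 on log2(FPKM + 0.1). The other alternatives beyond 1.5 times set the F2 against 1 parent, with all libraries kept in the fit. They gave 1071 calls against Qingyezhuma and 1661 against Zhongsizhu 1, as in the separate comparisons above. Without the 4 low libraries the count of F2 against parents was 3909. Both parents lay outside the F2 range for 896 gene models, and for 539 on FPKM values (38 below and 501 above the F2), a fall in the number below that was not seen without the 4 low libraries (577 below, 501 above). The number of candidates whose interval held 25%, 53, was 134 with at least 5 CPM and 26 with at least 50 CPM in the expressing parent, where more and fewer candidates entered (466 and 88), and stayed within 1.5 times under the other 6 alternatives. Except for these and the fold minimum, the cause was not tested. Of 127 recomputed values of the 7 named genes of both edgeR comparisons, 19 lost the threshold, 0 reversed and the others kept both direction and threshold. The gene model whole_GLEAN_10025661 and whole_GLEAN_10016669 kept theirs in all 19. No alternative of the 4 comparisons of gene lists was run, since no list could be matched. No paired analysis was possible because the groups share only replicate number 1. A gene model with no count in a parent may still lie at up to 0.174 CPM in Qingyezhuma or 0.238 CPM in Zhongsizhu 1.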

Other observations

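The comparison with random and adjacent pairs of F2 libraries was set up before its result was seen (the number of pairs was reduced afterwards to save computing time), and all other tests in this part were chosen after. The expression of many gene models followed the number in the F2 titles, whose meaning the labels do not state. The absolute correlation of log2 CPM with the title number was over 0.5 for 604 of 18657 gene models (445 positive, 159 negative), and for 0 in each of 100 permutations of the numbers. Without the 4 libraries with a low table total it was over 0.5 for 748. The strongest positive relation, found by searching all gene models of at least 20 CPM, was whole_GLEAN_10015603 (Pearson r = 0.82, Spearman rho = 0.83, permutation p = 1e-05 for each, the smallest the resamples can give; r = 0.82 without the 2 outermost libraries). It was at 67.1 ± 18.4 CPM in title numbers up to 37 (SD, n = 37) and 170.6 ± 46.9 CPM in those from 75 (SD, n = 37), and at 29.3 and 29.8 CPM in the parents. The strongest negative one, whole_GLEAN_10014670 (r = -0.76, rho = -0.77, permutation p = 1e-05 for each; r = -0.75 without the 2 outermost), was at 298.3 ± 110.5 and 145.5 ± 41.2 CPM (SD, n = 37 each), and at 268.2 and 241.6 CPM in the parents.

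F2 samples 32, 42, 45 and 69, with 4401589, 1349180, 1135995 and 4937283 counts, held the highest levels of the gene models of largest spread among those with an F2 mean of at least 20 CPM. The gene model whole_GLEAN_10001641 was at 1404.1, 1445.8, 1438.9 and 741.9 CPM in them and at most 11.8 CPM in any other F2 library. In the same 4 libraries whole_GLEAN_10000423 was at 473.1, 328.6, 2227.6 and 554.2 CPM, against at most 103.7 CPM elsewhere in the F2.

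Both parents lay apart from the F2 on the same side for many gene models. Chance is argued against for the 3482 calls by random pairs of F2 libraries in the parents' place: 1 of 23 pairs, the parents themselves, gave as many, and the highest other, which included F2 sample 45, gave 915. With 22 random pairs, 1 of 23 is the smallest share this comparison can give. A linear drift along the title numbers is argued against as the whole cause for the 896 gene models with both parents outside the F2 range. Of these, 8.6% (exact 95% interval 6.8 to 10.6%) had an absolute correlation with the title number over 0.5, and 403 had one under 0.2. A contribution stays open: among all tested gene models the share over 0.5 was lower, at 3.2%. The parents were also on the side of the low numbers in 69.1% of the 896. Steps or other courses along the numbers that are not linear were not tested for these gene models and stay open. The scaling is argued against as the cause for the 470 with both parents above the F2, with at least 501 under RLE size factors and on FPKM values. For the 426 below, 377 were found under RLE size factors and 38 on FPKM values. The 38 rest on the 4 libraries with a low table total. Their FPKM sums were 484729, 295759, 249789 and 593280, against 1306758 and 1289429 in the parents. Without these 4 libraries 577 lay below on FPKM values and 575 with TMM, which argues against the scaling as the cause there. With all F2 libraries kept it stays open. A difference in handling of parents and F2 may produce the pattern and cannot be told apart from a biological difference such as non-additive expression, which was not tested: the labels name no batch, and 8 pairs with adjacent title numbers gave at most 255 calls.

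Of the 29 gene models missing from the same F2 libraries, 24 had ID numbers in the lowest 10% of those tested, as did 43 of the 52 other gene models that followed their share with r over 0.8. If each library came from 1 plant, an on-off locus with a recessive silent allele is argued against by the absence of a gap: 23.4% of the F2 libraries (exact 95% interval 15.9 to 32.4%) lay between 1/50 and 1/10 of Zhongsizhu 1. The series' design text speaks of families, and a library pooled from several plants would give such levels under 1 locus, so for pooled plants it stays open. An effect running along the title numbers, such as sampling order, may contribute, since the log2 shares of neighbouring numbers correlated at 0.24 (one-sided permutation p = 0.00407), with no overall trend detected (r = 0.01, p = 0.93 and rho = 0, p = 0.976, permutation tests; r = -0.01 without the 2 outermost). RNA from another source that also takes reads from the counted gene models stays open: the share was 9.59 to 26.25% in the 4 low libraries, its relation to the table total per FPKM denominator over all 111 was r = -0.35 and rho = -0.19 (permutation p = 1e-05 and 0.0483, adjusted over 3 relations 3e-05 and 0.145; r = -0.35 without the 2 outermost), and without the 4 it was r = -0.13 and rho = -0.09 (p = 0.196 and 0.336, adjusted 0.294 and 0.504; r = -0.12), so the relation rests on those 4. The share was not tested against the total counts, so a relation to them stays open. F2 samples 23, 44, 68, 12 and 18, with 5661739, 8060686, 8065851, 8884795 and 9809004 counts, were at 11.09, 7.249, 7.765, 2.355 and 9.627%. The F2 median was 0.99%. Not every library followed this order: F2 sample 17, with 12881922 counts, was at 0.1%. No biological source was tested, since no gene model has a name.

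Among the other candidates, gene models with close ID numbers differed in how far they were missing from the same libraries by the parent that expressed them, and a candidate explanation is linkage. For 7 pairs within 10 IDs expressed in the same parent the mean phi was 0.29 (-0.07 to 0.74, over 0.7 in 2 pairs), and for 6 pairs expressed in opposite parents it was -0.14 (highest 0.1, under 0 in 4 pairs), a difference of 0.43 that shuffling the profiles within each parent rarely reached (one-sided permutation p = 2e-05). Pairs over 200 IDs apart had mean phi of 0.02 and -0.01. The mean of the opposite-parent pairs lay below that of shuffled profiles (one-sided permutation p = 0.00947). Shared reads, or gene models that are parts of 1 gene, were not tested and stay open for the same-parent pairs. The hypothesis rests on these 7 and 6 pairs and on the unstated assumption that IDs follow genome order.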
